A study of Mus musculus with 4 samples.

How the data were processed

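Gene expression was measured by RNA sequencing of poly(A)-selected RNA in 4 libraries of CCE mouse ES cells, 2 with a hairpin against luciferase and 2 with a hairpin against Tex10. Libraries were made with the TruSeq RNA kit and read as 100-bp single ends on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.10, Bowtie2 2.1.0, Cufflinks 2.1.1 and the mouse build mm9, and the role and options of each, the annotation and the treatment of strand are not given in the sources used here. The deposited values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, given by the authors per library without pooling of replicates. Each library's table has the same rows, of which 23311 carry a gene name and the others do not. FPKM divides by the number of mapped fragments and keeps no count, so a few very abundant features can shift the values of all others. Very short features can take large FPKM, which affects sums of FPKM.

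Unnamed rows took 56.3% of summed FPKM in shLuci replicate 1, 71.6% in shLuci replicate 2, 70.8% in shTex10 replicate 1 and 68.8% in shTex10 replicate 2, mostly in rows with loci of at most 200 bp. These rows stayed out of the main test. The named rows summed to 613641.9, 632066.5, 525877.9 and 537691.6 FPKM in the same order. Rows that shared a gene name (445 names) were summed, which gave 22739 genes, and 357 rows name several genes, whose values cannot be divided between them. Depth could only be estimated in relative terms, from the smallest value above 0 among unnamed rows at 1065 locus lengths, taking it as 1 read: with shLuci replicate 1 as 100%, the others stood at 94.1%, 83.4% and 92.0%. Each estimate rests on the most frequent ratio to shLuci replicate 1 within a preset range. Only 22.9%, 11.8% and 10.9% of the lengths lay at that ratio, so the estimates are rough. The precision that depth gives to single values is unknown, so no counting intervals are given.

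Samples were grouped by the knockdown in the labels. Before the data were examined, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed. Genes with a mean FPKM of at least 1 over the 4 libraries (11883) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using eBayes with a variance trend, no replicate block, and Benjamini-Hochberg adjustment with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each Benjamini-Hochberg adjusted over the 27 lists. camera compares a list with the other genes, while fry asks whether its genes move on balance in 1 direction. Counts adjusted over the list alone used the members' p-values only. The lists covered core and naive pluripotency, neighbours of super-enhancers, formative and primed cells, trophectoderm, primitive endoderm, mesoderm, neuroectoderm, germ cells, the 2-cell-like state, partners of TEX10, TET and p300 cofactors, ribosome biogenesis, ribosomal proteins, snoRNA hosts, p53 targets, stress responses, hypoxia and glycolysis, sterol synthesis, cell cycle, interferon response, BMP, Wnt and LIF targets, fibroblasts, other cell types, imprinted genes, replication histones and housekeeping genes. They were written from general knowledge, and lists overlap where genes have several roles. A further 7 lists, described under the other observations, were chosen after the data were seen and are reported without genes of the fixed lists and named genes.

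The named genes were Tex10, the 12 genes with the largest log2 change in each direction among those past the threshold with both libraries of a group on the same side of both libraries of the other, up to 4 genes with the smallest p in each list, and Pou5f1, Sox2, Nanog, Esrrb, Klf4, Tet1, Tet2 and Ep300. Genes named besides these were chosen after their values were seen: Invs, Trp53, Eif1a, Tmem92, Zfp352, Arg2, Psmb5, Dux, Cdkn1a, Mdm2, Gata3, Ccnd1, P4ha2, the trophectoderm, mesoderm and imprinted genes given as exceptions to their lists, and the genes of the added lists. The fitted model was tested on simulated data for shTex10 against shLuci with 11883 genes: of 67 genes changed by 0.5 on the log2 scale 1.5% were called, of 71 changed by 1 45.1%, and of 62 changed by 2 85.5%, with 0 false calls. Only these genes changed in the simulation, with independent noise, while 51.6% of genes were called in the data. A larger share of calls loosens the Benjamini-Hochberg cutoff, so neither the shares called nor the 0 false calls carry over to the data.

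Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, median scaling, quantile normalization, rescaling to the same sum over all rows, eBayes without trend or with robust estimation, the replicate number as a block, the highest row per gene name and leaving out each library. Inclusion of unnamed rows, removal of 65 small RNA genes and rescaling to the same sum over named genes were added after the data were seen. Chromosome medians were set against 10000 random gene sets of the same size. Sequence checks used GENCODE M21 transcripts and no coordinates, since that annotation is of another build. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.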

Results

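RNA was sequenced from CCE cells, a mouse embryonic stem (ES) cell line of the 129SV strain, grown on gelatin in medium with 15% serum and leukemia inhibitory factor. The cells carried a short hairpin RNA against Tex10 (shTex10) or, as the control, against luciferase (shLuci), a firefly gene with no counterpart in mouse. Each group had 2 libraries, and the deposited values were FPKM for rows with a gene name (23311) and rows without. The series title places Tex10 in the control of super-enhancers, pluripotency and reprogramming, and the comparison asks which transcripts differ when Tex10 is depleted. Between 11533 and 12003 named genes reached an FPKM of 1 in each library. FPKM tables hold no read totals. Depth was roughly estimated from the value of a single read in unnamed rows, relative to shLuci replicate 1. It was 94.1% for shLuci replicate 2, 83.4% for shTex10 replicate 1 and 92.0% for shTex10 replicate 2.

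In shTex10, 15.7% of the Tex10 transcript remained, and a large part of the transcriptome differed from shLuci. Of the genes tested, 51.6% were called as deposited and 7.49% after rescaling to the same sum over all rows. Effects of the hairpin other than through Tex10 were not separated. Genes of the core pluripotency network, ribosome biogenesis, the cell cycle, glycolysis and sterol synthesis were lower in shTex10, and genes of the 2-cell-like state, p53 targets and trophectoderm markers were higher. These lists passed limma's camera with a preset correlation, and 0 lists passed with an estimated correlation (lowest Benjamini-Hochberg adjusted p = 0.357). The latter test rests on 2 residual degrees of freedom and can seldom pass over 27 lists. Zscan4d, a gene transcribed in the 2-cell embryo, rose 8.18-fold, from 12.4 ± 0.670 to 101 ± 4.62 FPKM (mean ± SD, n = 2 per group). Its value is uncertain, because near-identical copies share reads. Prdm14, a regulator of naive pluripotency, fell from 14.4 ± 0.3 to 3.92 ± 0.141 FPKM.

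The targeted gene was read first, since it checks the labels. Tex10 (XLOC_019228, mm9 chromosome 4, 48292673 to 48486356) measured 77.3 and 82.1 FPKM in the shLuci libraries and 11.6 and 13.4 FPKM in the shTex10 libraries. Its mean was 79.7 ± 3.44 FPKM in shLuci and 12.5 ± 1.21 FPKM in shTex10 (SD, n = 2 each), a log2 change of -2.58 (SE 0.10, limma with Benjamini-Hochberg adjusted p = 0.000143). Another row, that of Invs, overlaps this locus, and the sources do not say whether strand was used in assigning reads. All log2 changes are differences of log2(FPKM + 1), shTex10 minus shLuci, which understate the change of low genes.

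Of 11883 genes tested, 2350 were higher and 3779 lower in shTex10 (limma, Benjamini-Hochberg adjusted p under 0.05), and 711 were higher and 362 lower by at least 2-fold. Replicates lay closer together than groups: the Pearson correlation across genes was 0.990 in shLuci, 0.989 in shTex10 and between 0.941 and 0.946 across groups, with genes not being independent replicates. Both shTex10 libraries lay above both shLuci libraries for 3364 genes and below them for 5717, together 76.4% of the genes. For libraries that are exchangeable gene by gene, chance gives 33.3%. Both shTex10 libraries had lower named sums of FPKM than both shLuci libraries. An offset in scale can therefore separate genes as well, and the excess over 33.3% does not measure an effect of the knockdown. The series design calls the samples biological replicates and says nothing more of separate cultures, so p-values measure the spread between these samples. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.33.

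The balance of higher and lower genes depended on the scaling. Genes called higher made up 38.3% of all calls with FPKM as deposited and 62.9% (3239 higher, 1908 lower) with each library rescaled to the same sum over named genes, a scaling chosen after the data were seen. The median log2 change of all genes was -0.14 as deposited and 0.07 after that rescaling, which ended the calls of 7 of the 129 named genes past the test. Rescaling to the same sum over all rows left the median at -0.13 but enlarged the errors. Nanog had a log2 change of -0.65 (SE 0.43 in place of 0.09) and Tet1 of -0.87 (SE 0.43 in place of 0.08), and both lost their call (limma, Benjamini-Hochberg adjusted p = 0.525 and 0.275). That rescaling called 652 genes higher and 238 lower, 73.3% higher, and 58 of the 129 named genes lost their call, these 2 included. List medians are given both as measured and relative to the median of all genes. Subtracting that median did not remove the dependence on scaling. Between scalings the relative median ran from -0.47 to -0.20 for core pluripotency and from -0.46 to -0.22 for ribosome biogenesis. It ran from -0.51 to -0.26 for the partners of TEX10 and from -0.47 to -0.30 for the cell cycle. Sterol synthesis (-0.635 to -0.597) and p53 targets (1.11 to 1.26) varied less. The sign held in each of these lists.

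Pluripotency regulators were lower in shTex10. Of 16 core pluripotency genes, 11 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone, and the median log2 change was -0.61, or -0.47 relative to all genes. Pou5f1, the gene of Oct4, fell from 893 ± 63.1 to 575 ± 35.8 FPKM (n = 2 each, log2 change -0.64, SE 0.10). Nanog fell from 267 ± 14.5 to 169 ± 6.47 FPKM (log2 change -0.66, SE 0.09), and Fgf4, a growth factor gene of ES cells, from 60.6 ± 0.681 to 22.0 ± 0.208 FPKM (log2 change -1.42, SE 0.08). Sox2 did not pass the test, at 187 ± 19 and 156 ± 3.65 FPKM (log2 change -0.26, limma with Benjamini-Hochberg adjusted p = 0.0829), and its change was 0.08 under quantile normalization. With the replicate number as a block Sox2 passed (limma, Benjamini-Hochberg adjusted p = 0.00480). The core list as a whole was lower than other genes (limma's camera, Benjamini-Hochberg adjusted p = 0.00365), with adjusted p = 0.357 with an estimated correlation.

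Among 23 naive pluripotency genes, 15 fell, 4 rose and 4 did not pass, the same counts as adjusted over the list alone, with a median log2 change of -0.49, or -0.35 relative to all genes. On the log2(FPKM + 1) scale the largest falls in this list were those of Nr0b1 (Dax1) from 108 ± 16.6 to 21.9 ± 4.16 FPKM, Tcl1 from 60.9 ± 8.35 to 13.1 ± 1.68 FPKM and Lefty2, a Nodal antagonist, from 248 ± 13.5 to 75.2 ± 4.88 FPKM (n = 2 each). Esrrb fell by 0.67 (SE 0.12) and Klf4 by 0.42 (SE 0.09) on the log2 scale. Dppa3, which marks naive cells and germ cells, rose from 13.5 ± 0.170 to 33.7 ± 2.07 FPKM. The naive list as a whole missed the threshold (limma's camera, Benjamini-Hochberg adjusted p = 0.0675), a call that changed when single libraries were left out. With an estimated correlation camera gave the list an adjusted p = 0.459.

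Genes beside which super-enhancers have been described in ES cells were lower, with 14 of 20 fallen, 1 risen and 5 not past the test, the same as adjusted over the list alone. Of these 20 genes, 14 also belong to the core or naive list. The median log2 change was -0.53, or -0.40 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 0.00285), with adjusted p = 0.357 with an estimated correlation. Zfp42 (Rex1) fell from 613 ± 1.91 to 372 ± 3.06 FPKM. Under quantile normalization the calls of this list (adjusted p = 0.0854 from limma's camera), of the core list (0.104) and of the genes Pou5f1 (0.149), Esrrb (0.0599) and Klf4 (0.0586) were lost. Klf4 also lost its call without shLuci replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0637) and after the named-gene rescaling (0.135).

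**Figure D1:**
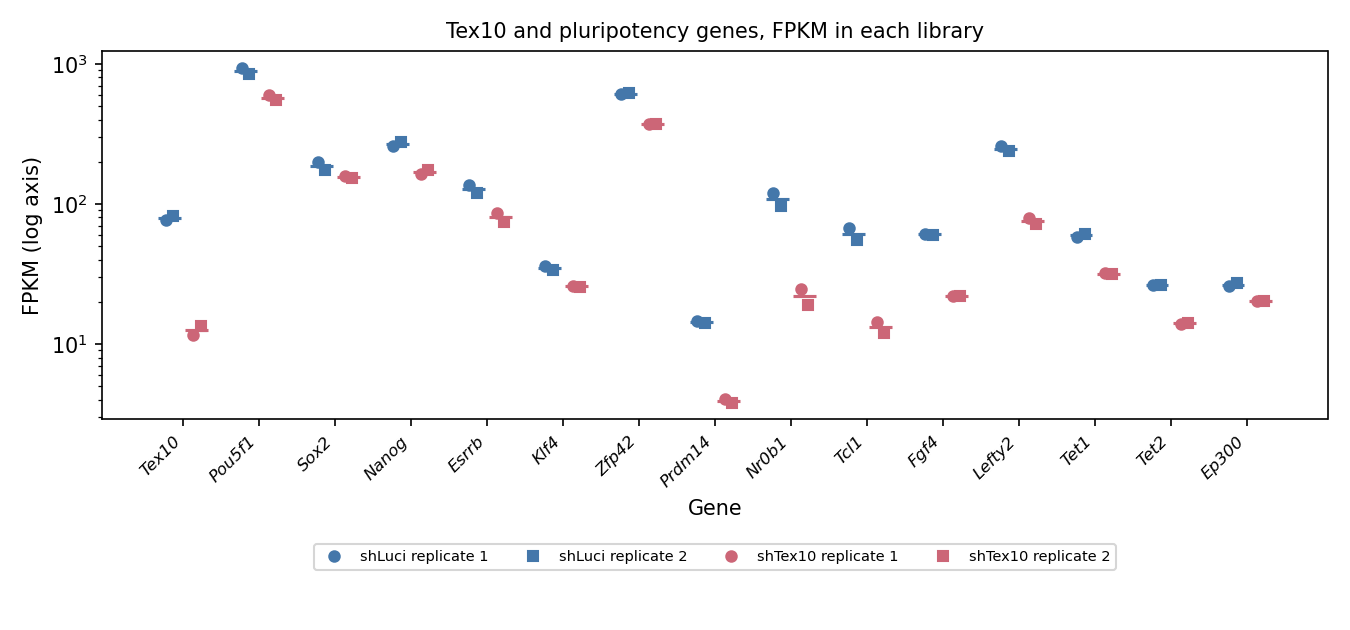
FPKM (log axis) of Tex10 and 14 pluripotency and cofactor genes in each library, with circles for replicate 1, squares for replicate 2 and bars for the group means (n = 2). Tex10 lay at 77.3 and 82.1 FPKM in shLuci and at 11.6 and 13.4 FPKM in shTex10, and the shTex10 values of each gene drawn lay below its shLuci values, by a margin that passed the test without a replicate block for each but Sox2.

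Of 16 genes for TET enzymes, p300 and other chromatin and enhancer cofactors, including the deacetylase gene Hdac1 and the DNA glycosylase gene Tdg, 9 fell, 0 rose and 7 did not pass, over all genes and adjusted over the list alone. Tet1, which oxidizes 5-methylcytosine, fell from 59.7 ± 1.74 to 31.7 ± 0.457 FPKM (log2 change -0.89, SE 0.08) and Tet2 from 26.4 ± 0.193 to 14.0 ± 0.121 FPKM (log2 change -0.87, SE 0.08; n = 2 each). Ep300, the gene of the acetyltransferase p300, fell by 0.38 (SE 0.09) on the log2 scale. The list was lower than other genes, at a median of -0.34, or -0.21 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 0.0103), with adjusted p = 0.357 with an estimated correlation. The list call was lost without shTex10 replicate 1 (adjusted p = 0.0997 from limma's camera), without shTex10 replicate 2 (0.0812), under quantile normalization (0.0707) and after the all-row rescaling (0.0988). Ep300 lost its call without shLuci replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0958), without shTex10 replicate 1 (0.0532), without shTex10 replicate 2 (0.0591), under quantile normalization (0.0622) and after the named-gene rescaling (0.175).

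Transcripts of genes listed as partners of TEX10 fell with Tex10. The list was drawn up around the PELP1-TEX10-WDR18 complexes, which act in ribosome assembly. It also holds Erh and Prmt1, and the place of each listed gene in these complexes was not checked. All 9 tested genes of the list fell, also when adjusted over the list alone, at a median log2 change of -0.65, or -0.51 relative to all genes. Senp3, a SUMO protease gene, fell from 141 ± 6.83 to 77.5 ± 7.47 FPKM and Nol9 from 63.6 ± 1.91 to 42.8 ± 1.68 FPKM (n = 2 each). The list was lower than other genes (limma's camera, Benjamini-Hochberg adjusted p = 0.00380), with adjusted p = 0.357 with an estimated correlation. Prmt1 lost its call under quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0675).

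Ribosome biogenesis genes moved in the same direction. Of 33 tested, 25 fell, 0 rose and 8 did not pass, and 27 fell when adjusted over the list alone. The median log2 change was -0.59, or -0.46 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 2.16e-05), with adjusted p = 0.357 with an estimated correlation. Tcof1, the gene of the nucleolar protein treacle, fell from 61.9 ± 0.483 to 29.1 ± 1.25 FPKM, and Polr1b, a subunit gene of RNA polymerase I, from 39.0 ± 0.750 to 22.0 ± 0.654 FPKM (n = 2 each). Of 38 ribosomal protein genes, 10 fell, 0 rose and 28 did not pass, 1 fell adjusted over the list alone, and the list was not called (limma's camera, Benjamini-Hochberg adjusted p = 0.0851). The median of the ribosomal protein genes was -0.18, or -0.05 relative to all genes, and its sign flipped between scalings, which ran from -0.18 to 0.05. Rpl3 fell from 1695 ± 87.4 to 998 ± 58.1 FPKM, whereas Rpl5 went from a log2 change of -0.41 to 0.03 under quantile normalization. Among 8 snoRNA host transcripts 4 fell, 0 rose and 4 did not pass, with 5 lower when adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.0651). Snhg5 was the host with the smallest p, at 171 ± 8.28 and 70.3 ± 4.12 FPKM.

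Genes of the 2-cell-like state, a rare state of ES cells that resembles the 2-cell embryo, rose most of all lists. Of 15 tested, 14 rose, 0 fell and 1, Eif1a, did not pass, with the same counts adjusted over the list alone. The median log2 change was 2.65, or 2.78 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 7.29e-12), with adjusted p = 0.357 with an estimated correlation. Tdpoz3 rose from 5.85 ± 0.523 to 50.1 ± 0.176 FPKM, Zscan4a from 20.2 ± 1.23 to 134 ± 3.63 FPKM and Zscan4f from 20.2 ± 2.27 to 155 ± 9.36 FPKM (n = 2 each). Values of single Zscan4, Tdpoz and Usp17l genes are uncertain, because near-identical copies share reads. The counts and the p-value at the preset correlation of 0.01 take these copies as separate genes, while the list's estimated correlation was 0.574. Summed over each family, FPKM rose 7.24-fold for Zscan4, 9.22-fold for Tdpoz and 5.81-fold for Usp17l, sums to which no test was applied.

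Targets of the tumour suppressor p53 rose. Of 29 tested, 23 rose, 1 fell and 5 did not pass, the same as adjusted over the list alone, at a median log2 change of 0.99, or 1.12 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 3.61e-11), with adjusted p = 0.357 with an estimated correlation. Perp, a desmosome gene, rose 5.79-fold from 22.2 ± 0.185 to 129 ± 2.55 FPKM, Plk2 rose 4.47-fold from 36.9 ± 3.41 to 165 ± 10.7 FPKM and Btg2, an antiproliferative gene, rose 3.79-fold from 18.8 ± 0.686 to 71.3 ± 0.699 FPKM (n = 2 each). The gene that fell was Ccnd1 (cyclin D1), which promotes cell division, with a log2 change of -1.09. The transcript of p53 itself, Trp53, named after its value was seen, did not pass the test (log2 change -0.22, limma with Benjamini-Hochberg adjusted p = 0.222).

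Trophectoderm markers were mostly higher. Of 18 tested, 14 rose and 4 fell, the same as adjusted over the list alone, at a median log2 change of 0.97, or 1.11 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 3.84e-05), with adjusted p = 0.357 with an estimated correlation. Cdh3 (P-cadherin) rose from 10.2 ± 0.687 to 41.0 ± 4.51 FPKM, Krt8 from 132 ± 0.0856 to 289 ± 7.06 FPKM and Ascl2, a transcription factor gene of the trophoblast, from 1.37 ± 0.286 to 8.69 ± 1.77 FPKM (n = 2 each). The 4 that fell were Tspan8, Ets2, Bmp4 and Tead4. In the same libraries, 5 of 6 tested markers of blood, endothelium, muscle and epithelium were higher, 0 lower and 1 not past the test, also adjusted over the list alone (median log2 change 0.54, or 0.68 relative to all genes; limma's camera, Benjamini-Hochberg adjusted p = 0.00248), with adjusted p = 0.361 with an estimated correlation. These included Krt5, a keratin gene of basal epithelia, at 0.0857 ± 0.0121 and 3.16 ± 0.375 FPKM, and Tek, an endothelial receptor gene, at 2.65 ± 0.130 and 9.17 ± 0.347 FPKM. Cdh1 (E-cadherin), another of the 5, was already at 119 ± 0.655 FPKM in shLuci, against 174 ± 0.276 FPKM in shTex10. Only 6 of the 18 genes listed were tested, and Krt5 reached the filter only through its shTex10 values, so a broad rise of such markers is not shown.

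**Figure D2:**
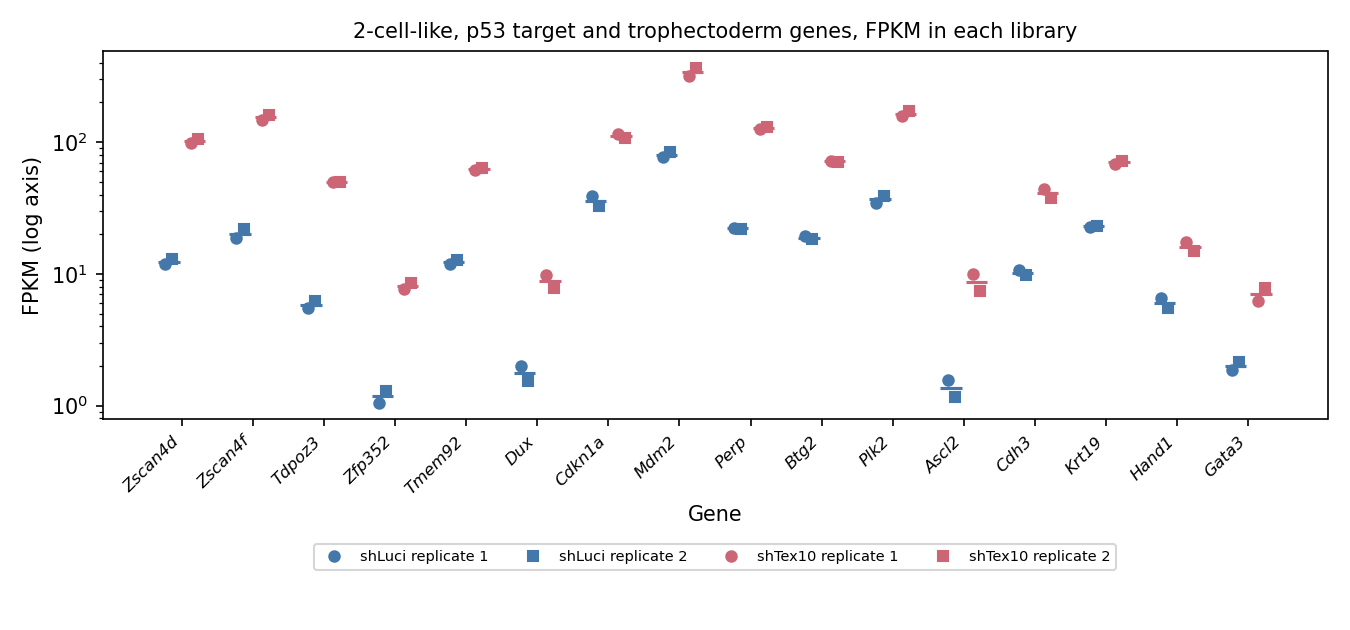
FPKM (log axis) of 2-cell-like genes, p53 targets and trophectoderm markers in each library, with circles for replicate 1, squares for replicate 2 and bars for the group means (n = 2). Each gene drawn was higher in both shTex10 libraries than in both shLuci libraries, Zscan4d by 8.18-fold and Perp by 5.79-fold, and Zfp352, Tmem92, Dux, Cdkn1a, Mdm2 and Gata3 were chosen for the plot after their values were seen.

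Replication-dependent histone mRNAs, most of which lack a poly(A) tail and which therefore report on poly(A) selection, were higher in shTex10. Of 13 tested, 8 rose, 0 fell and 5 did not pass, and 10 rose adjusted over the list alone, at a median log2 change of 0.62, or 0.75 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 0.000380), with adjusted p = 0.357 with an estimated correlation. Histone genes made up 0.0140% and 0.0125% of the named FPKM in shLuci and 0.0304% and 0.0266% in shTex10. Hist1h4i rose from 10.8 ± 0.898 to 19.7 ± 2.20 FPKM (n = 2 each), and single histone genes share reads with near-identical copies. The cell-cycle and DNA replication genes moved the other way in these libraries.

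Of 32 cell-cycle genes, 26 fell, 0 rose and 6 did not pass, and 27 fell adjusted over the list alone. Ccne1 (cyclin E1) fell from 86.4 ± 1.54 to 25.8 ± 1.01 FPKM, Pcna, the sliding clamp gene of DNA replication, from 506 ± 10.3 to 251 ± 20.8 FPKM and Aurkb from 31.0 ± 0.120 to 13.9 ± 1.04 FPKM (n = 2 each). The median log2 change was -0.60, or -0.47 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 2.73e-05), with adjusted p = 0.357 with an estimated correlation.

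Sterol synthesis genes fell in 16 of 17 cases, with 1 higher and the same counts adjusted over the list alone. Cyp51, a sterol demethylase gene, fell from 20.5 ± 1.37 to 6.37 ± 0.873 FPKM and Insig1 from 56.0 ± 2.48 to 23.0 ± 1.98 FPKM (n = 2 each). The higher value belonged to a row shared by Lss and Mcm3ap, so the change cannot be assigned to Lss. The list median was -0.76, or -0.63 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 0.000205), with adjusted p = 0.357 with an estimated correlation.

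Glycolysis and hypoxia-response genes were also lower, with 18 of 24 fallen, 1 risen (P4ha2, a collagen hydroxylase gene) and 5 not past the test, the same as adjusted over the list alone. Ldha (lactate dehydrogenase A) fell from 999 ± 46.2 to 371 ± 15.3 FPKM and Pgk1 from 651 ± 22.7 to 306 ± 18.6 FPKM (n = 2 each). The median log2 change was -0.71, or -0.57 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 0.000380), with adjusted p = 0.361 with an estimated correlation. Pgk1 and Gapdh are among 21 genes commonly used as expression references, of which 9 fell, 0 rose and 12 did not pass, also adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.0818). The median of these reference genes ran from -0.21 as deposited to 0.01 under other scalings, so its sign flipped.

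Stress-response genes went both ways. Of 25 targets of ATF4 and the unfolded protein response, 7 rose, 13 fell and 5 did not pass, the same adjusted over the list alone, and the list was not called (limma's camera, Benjamini-Hochberg adjusted p = 0.387). Atf3, a stress-induced transcription factor gene, rose from 2.56 ± 0.260 to 12.7 ± 0.297 FPKM, while the serine synthesis genes Phgdh and Psat1 fell, with log2 changes of -1.67 (SE 0.11) and -1.52 (SE 0.09). Of 9 interferon-stimulated genes, a known response to double-stranded RNA, 2 rose, 3 fell and 4 did not pass, over all genes and adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.387). Oas1a, one of the 3, went from 3.19 ± 0.00224 to 0.649 ± 0.0947 FPKM, and the list median ran from -0.20 to 0.03 between scalings, with a flip of sign that was absent relative to all genes (-0.11 to -0.04). Ddx58, another of the 3, lost its call under median scaling, quantile normalization, both rescalings and no filter on low values, and without shLuci replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.197) or shTex10 replicate 1 (0.0502).

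Targets of BMP, Wnt and LIF signalling also went both ways, with 8 of 18 higher, 5 lower and 5 not past the test, and 6 lower adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.0840). Id2, a BMP target, rose from 13.4 ± 1.25 to 42.0 ± 3.79 FPKM and Spry4, a feedback inhibitor of FGF signalling, fell from 26.3 ± 2.33 to 8.26 ± 0.476 FPKM (n = 2 each). Without shLuci replicate 1 this list passed (limma's camera, Benjamini-Hochberg adjusted p = 0.0345).

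Lineage markers were split. Of 7 primitive streak and mesoderm genes, 5 rose, 1 (Bmp4) fell and 1 did not pass, with 6 higher and 1 lower adjusted over the list alone (median log2 change 0.69, or 0.83 relative to all genes; limma's camera, Benjamini-Hochberg adjusted p = 0.00502), with adjusted p = 0.459 with an estimated correlation. Hand1 rose from 5.99 ± 0.740 to 16.1 ± 1.78 FPKM and Snai1, a repressor of E-cadherin, from 2.46 ± 0.526 to 8.55 ± 1.75 FPKM (n = 2 each). With no filter on low values this call was lost (limma's camera, Benjamini-Hochberg adjusted p = 0.185). Of 12 primitive endoderm genes, 6 rose, 2 fell and 4 did not pass, with 6 higher and 3 lower adjusted over the list alone (median log2 change 0.31, or 0.44 relative to all genes; limma's camera, Benjamini-Hochberg adjusted p = 0.0442), with adjusted p = 0.459 with an estimated correlation. Sparc rose from 120 ± 5.78 to 228 ± 4.38 FPKM and Lama1, a laminin gene, fell from 9.19 ± 0.0320 to 2.38 ± 0.129 FPKM. That call was lost without any single library, at adjusted p between 0.0946 and 0.294 (limma's camera, Benjamini-Hochberg).

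Neural and ectoderm markers went in both directions, with 4 of 11 higher, 6 lower and 1 not past the test, also adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.714). Neurod1, a proneural gene, rose from 2.33 ± 0.172 to 22.0 ± 2.14 FPKM, and Pax6, a gene of eye and brain development, fell from 6.18 ± 0.543 to 0.673 ± 0.0528 FPKM (n = 2 each). Of 13 genes of formative and primed pluripotency, 1 rose, 5 fell and 7 did not pass, also adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.389). Their median was -0.09 but 0.05 relative to all genes, the mean was -0.42, and the sign of the median flipped between scalings. Zic2 fell from 26.5 ± 3.83 to 7.57 ± 0.836 FPKM.

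Germ cell genes counted 5 higher, 3 lower and 9 not past the test of 17, also adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.172), with Taf7l at 2.77 ± 0.305 and 8.42 ± 0.928 FPKM. Fibroblast markers, which would report feeder or stromal cells, counted 3 higher, 3 lower and 6 not past of 12, also adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.369), and their median ran from -0.03 to 0.25 between scalings, with a flip of sign that was absent relative to all genes (0.05 to 0.18). Tagln, a marker of smooth muscle and fibroblasts, rose from 82.0 ± 0.997 to 137 ± 1.38 FPKM, and Col1a2, a type I collagen gene, fell from 12.7 ± 1.38 to 7.37 ± 0.705 FPKM (n = 2 each).

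Imprinted genes, whose expression varies between ES cell cultures, were on balance higher. Of 19 tested, 10 rose, 3 fell and 6 did not pass, with 11 higher and 4 lower adjusted over the list alone, at a median log2 change of 0.37, or 0.50 relative to all genes (limma's camera, Benjamini-Hochberg adjusted p = 0.00531), with adjusted p = 0.357 with an estimated correlation. H19, a maternally expressed non-coding RNA, rose 4.59-fold from 41.0 ± 4.80 to 188 ± 18.2 FPKM, and the paternally expressed Peg10 rose 2.32-fold from 104 ± 6.48 to 241 ± 1.33 FPKM (n = 2 each). The 3 that fell were Phlda2, Grb10 and the row shared by Snrpn and Snurf.

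**Figure D3:**
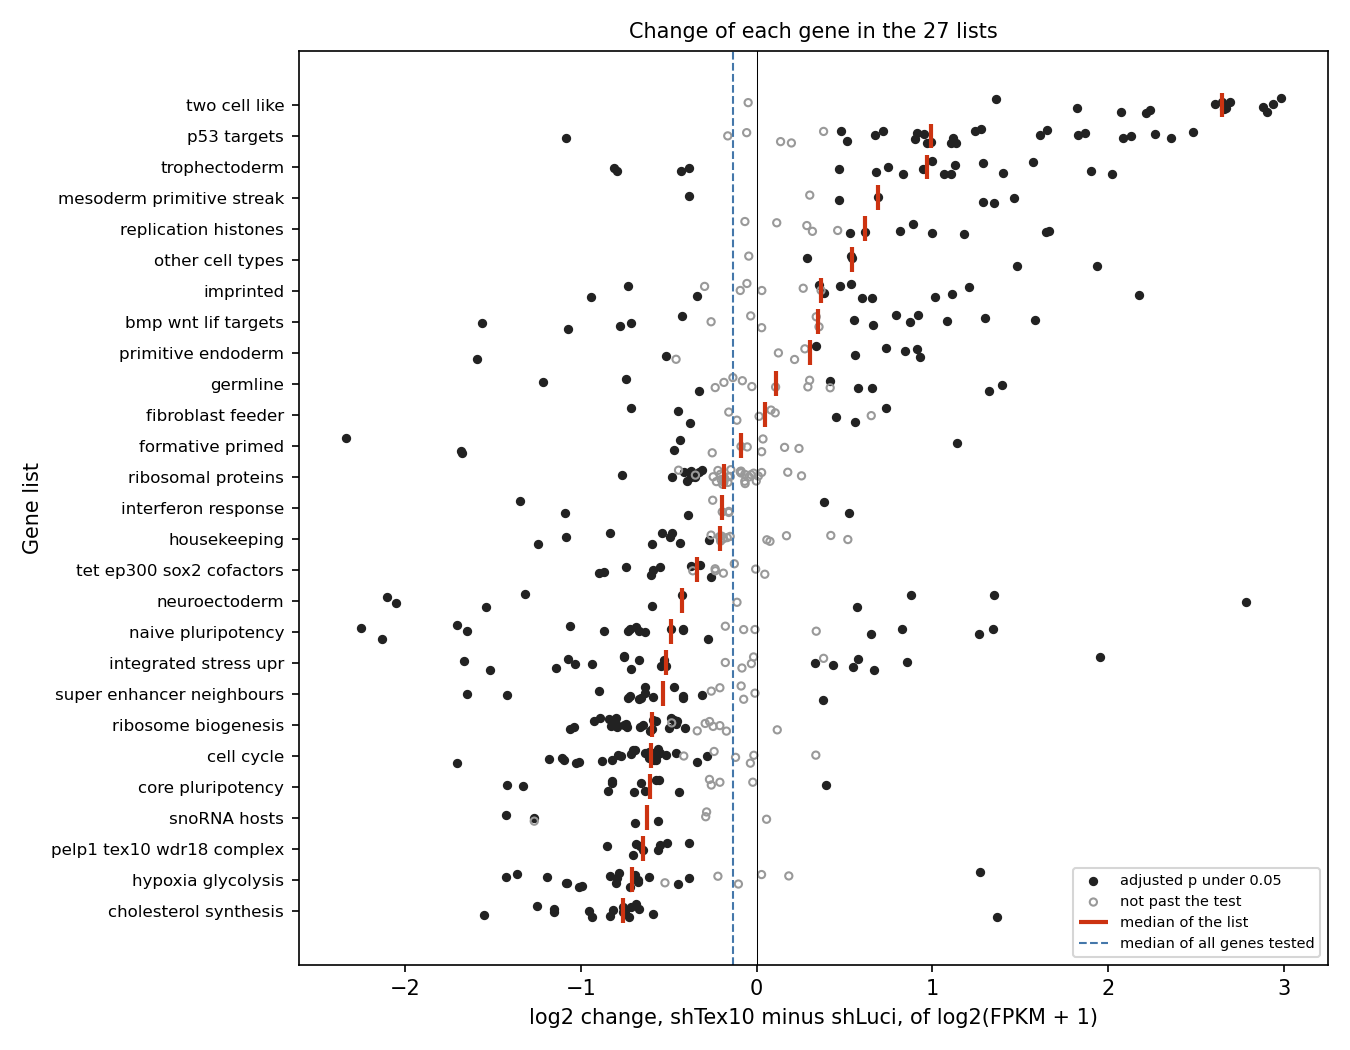
Log2 change of log2(FPKM + 1), shTex10 minus shLuci, for each tested gene of the 27 lists: filled points passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, open points did not, red bars mark list medians and the dashed line marks the median of all genes, -0.14. The medians run from -0.76 for sterol synthesis to 2.65 for the 2-cell-like genes, and those of the formative, housekeeping and ribosomal protein lists change sign between scalings also relative to all genes, those of the fibroblast and interferon lists only as measured.

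In total 8 lists were higher and 8 lower in shTex10, and 11 were not called. With an estimated correlation, camera called 0 lists, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.357. That test has 2 residual degrees of freedom, so 0 calls do not show that correlation explains the lists. The p53 targets had an estimated correlation of -0.0175, under the preset 0.01, yet camera's unadjusted p went from 2.67e-12 to 0.0156. The 2-cell-like list had an estimate of 0.574. limma's fry, which does not compare a list with the other genes, called 21 lists. With 51.6% of all genes called, these calls do not counter the 0 calls of camera. The housekeeping list was among them (limma's fry, Benjamini-Hochberg adjusted p = 0.00867). Replication histones (0.0833) and primitive endoderm (0.0967), called higher by camera at the preset correlation, were not.

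Besides the 2-cell-like genes, the largest rises past the test on the log2(FPKM + 1) scale were those of Ms4a10 from 1.59 ± 0.541 to 31.7 ± 2.41 FPKM (log2 change 3.67, SE 0.16), Apol8 from 0.750 ± 0.141 to 15.8 ± 0.972 FPKM (log2 change 3.27) and Matn1, a cartilage matrix gene, from 0.963 to 16.3 FPKM (log2 change 3.14, SE 0.16; n = 2 each). Pvrl4, Rgs14, Cpz, Gm10696 and Tap1, the last a peptide transporter gene of antigen presentation, followed with log2 changes from 2.79 to 2.97. By the ratio of mean FPKM the order differs, with Krt5 at 36.9-fold and Rgs14 at 28.7-fold above Ms4a10 at 19.9-fold. The largest fall of a protein-coding gene on the log2(FPKM + 1) scale was that of Pfas (XLOC_004445, mm9 chromosome 11, 68799016 to 68822155), an enzyme gene of purine synthesis, from 349 ± 11.7 to 23.3 ± 0.471 FPKM (log2 change -3.85, SE 0.08, limma with Benjamini-Hochberg adjusted p = 6.48e-05). Its fall exceeded that of Tex10 itself, and by the ratio of mean FPKM Fgf17 fell more (16.1-fold, Pfas 15.0-fold). Sfrp1, a Wnt antagonist gene, fell from 17.3 ± 0.527 to 1.56 ± 0.00107 FPKM, Fgf17 from 10.1 ± 1.46 to 0.630 ± 0.169 FPKM, Gfpt2 from 24.8 ± 0.553 to 3.23 ± 0.0517 FPKM, Tcf15 from 37.8 ± 1.30 to 6.81 ± 2.04 FPKM and Mov10, an RNA helicase gene, from 47.6 ± 1.57 to 9.38 ± 1.26 FPKM. Small RNA genes are measured poorly in such libraries. Mir1199 had a log2 change of -2.96, Mir215 was at 101 and 104 FPKM, Mir7-1 at 324 and 168 FPKM and Snora62 at 33.6 and 40.3 FPKM in the shLuci libraries, and the last 3 were listed at 0 in both shTex10 libraries.

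Whole chromosomes differed little. Median log2 changes per chromosome lay between -0.17 for chromosome 5 and -0.04 for chromosome 12, and 3 of 20 lay outside the central 95% of 10000 random gene sets of the same size, chromosomes 1 and 12 above and chromosome 5 below. That number was 2 without shLuci replicate 1 and without shTex10 replicate 2 (chromosomes 7 and 12 in both cases, with 1 and 5 inside), 5 without shLuci replicate 2 and 6 without shTex10 replicate 1.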

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

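The tests of rows without a gene name, of the scaling, of shared reads and of hairpin matches were chosen only after the results were seen.

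A signal lay in rows that carry no gene name and that the comparisons above do not use: of 1770 such rows with a mean FPKM of at least 1, 637 were higher and 233 lower in shTex10 (limma, Benjamini-Hochberg adjusted p under 0.05).

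More named genes fell than rose with FPKM as deposited. In a seed effect the hairpin's first bases bind many 3' UTRs. A seed effect large enough for the whole surplus of lower genes was argued against, for the strand that pairs with the Tex10 mRNA. In 3' UTRs of lower genes, no 7-base word of that mRNA had an excess accounting for more than 4.2% of them (SE 1.34). The surplus of lower over higher genes is 39.5% of the 3408 lower genes searched (2061 higher genes searched). A seed effect on a smaller share of the lower genes stays possible. The hairpin's other strand was not searched. The scaling of the libraries could account for the balance, since the median log2 change of all genes was -0.14 as deposited and 0.0666 after rescaling over named genes, where 62.9% of calls were higher. A change in total RNA per cell cannot be read from FPKM, which carries no absolute scale, and was not tested.

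Genes of the 2-cell-like state rose. Reads moved between near-identical copies were argued against as the whole cause: the 4 listed genes with under 10% of their 50-base words shared with other genes had a median log2 change of 1.72 (Tmem92, Zfp352 and Arg2 higher, Eif1a not past the test), and the lowest log2 change of a family sum was 2.48. The scaling was argued against too, since the median log2 change of the list was at least 2.44 in each of 5 scalings. A wider 2-cell-like state in the depleted cells is a hypothesis, found and tested on the same data, and whether more cells enter it or each cell expresses more may be told by single-cell data only.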

How the results depend on the processing

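The inclusion of unnamed rows, the removal of small RNA genes and the rescaling over named genes were chosen after the results were seen, and the other alternatives before.

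The Tex10 level kept its direction and its call in each alternative, and the log2 change of the Tex10 level ran from -2.67 to -2.49 when 1 library was left out, where a lone library is assumed to vary like the others. Leaving out 1 library gave 2109 to 2265 higher and 3210 to 3499 lower genes, 658 to 772 higher and 361 to 423 lower by at least 2-fold, 7 to 8 lists higher, 9 to 10 lower and 2 to 6 chromosomes outside. A mean FPKM of at least 5, which tests fewer genes, gave 1292 higher genes, 397 by at least 2-fold, and 4 lists higher. Rescaling over all rows, most of whose sum lies in unnamed rows, enlarged the errors (Nanog, log2 change -0.65, SE 0.43 in place of 0.09) and gave 652 higher (454 by at least 2-fold) and 238 lower genes (172), and rescaling over named genes 1908 lower genes (235) and 1111 higher by at least 2-fold. With unnamed rows 1157 were higher by at least 2-fold, since more rows were tested. Quantile normalization ended the calls of 4 lists, in both directions, and left 5 lower, and an estimated correlation left 0 in either direction. Rpl5 turned to a log2 change of 0.0309 under quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.763), and the cause was not tested. Besides the all-row rescaling, 11 of the 129 named genes lost their call in some alternative. The pseudocount of 0.1 moved the lowest Pearson correlation within groups to 0.9846 and the highest between groups to 0.9314, and no filter moved them to 0.995 and 0.975, both by construction. With the replicate number as a block, 3210 genes were higher and 5709 lower, Sox2 passed (limma, Benjamini-Hochberg adjusted p = 0.00480) and so did the snoRNA hosts. The differences between replicates correlated across genes between the groups (Pearson 0.331, Spearman 0.706), so replicates 1 and 2 differed partly alike in both groups. The labels name no shared day or batch, and 2 pairs do not show pairing. Depth is known only in relative terms, which limits statements on low genes and on those listed at 0.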

Other observations

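The 7 gene lists and all tests in this part were chosen after the results were seen.

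Each list is given without the genes that belong to a list fixed beforehand or were named by the rule, since their changes had been read when the lists were drawn up. The changes of the other genes had been computed by then too. The p-values below therefore describe lists chosen on the same data and are not independent evidence. Of 24 tested epithelial junction and keratin genes 8 were left out on this ground, among them Pvrl4, Perp, Krt8 and Krt19. Of the other 16, 10 rose, 0 fell and 6 did not pass (median log2 change 0.50; limma's camera, Benjamini-Hochberg adjusted p over the 7 lists = 0.000278), with adjusted p = 0.199 with an estimated correlation. Sfn rose by 2.18 and Cldn4 by 1.28 on the log2 scale. Targets of the Hippo pathway effector YAP rose in 14 of 16 cases, with 0 lower and 2 not past, 1 gene being left out (median log2 change 1.19; limma's camera, Benjamini-Hochberg adjusted p = 1.8e-08), with adjusted p = 0.199 with an estimated correlation. The gene left out was the only one of the 17 tested that fell. Cyr61 changed by 2.59, Ctgf by 1.48 and Ankrd1 by 1.65 on the log2 scale.

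Of 10 serine and one-carbon metabolism genes, with 4 left out that include Phgdh and Psat1, 7 fell, 0 rose and 3 did not pass (median log2 change -0.92; limma's camera, Benjamini-Hochberg adjusted p = 0.00381), with adjusted p = 0.199 with an estimated correlation, and Mthfd1l changed by -1.39. Proteasome subunit genes fell in 20 of 25 cases, with 0 higher and 5 not past and 1 left out (median log2 change -0.59; adjusted p = 0.000278 from limma's camera), with adjusted p = 0.372 with an estimated correlation. With the gene left out restored, the proteasome median relative to all genes ran from -0.44 to -0.17 between scalings. Without Pfas, which prompted the list, purine synthesis genes counted 7 lower, 1 higher and 3 not past of 11 (median -0.70; adjusted p = 0.0354 from limma's camera), with adjusted p = 0.372 with an estimated correlation. Polycomb genes (10 lower, 1 higher and 7 not past of 18; adjusted p = 0.0688 from limma's camera) and DNA methylation genes (5 lower, 2 higher and 1 not past of 8; adjusted p = 0.348) were not called as lists, and Uhrf1 changed by -1.19.

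Psmb5, a proteasome gene, was at 292 and 6490 FPKM in the shLuci libraries and at 209 and 5762 FPKM in the shTex10 libraries, in each group higher in replicate 2. Of 6 genes that differed at least 4-fold between replicates in both groups, 3 did so in the same direction.

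Pfas fell more than Tex10, the gene targeted. For the hairpin strand that pairs with the Tex10 mRNA, a near-perfect match was argued against. Any 19 bases of the Tex10 and Pfas mRNAs differ by at least 3 mismatches. Of 200 mRNAs of like length, 184 reach or go below that number. Only the longest transcript of each gene was compared, and the hairpin's other strand was not searched. Reads lost to another row were argued against, with 0 other rows within 5000 bp of the locus. A joint fall of purine synthesis genes of the size seen in Pfas was argued against as well, since the lowest log2 change among the other 11 was -1.13 and their median -0.70. Hypotheses that stay open are a partial match of the hairpin, whose sequence is not used here, a match of its other strand, and a regulation of Pfas by Tex10. Hairpins of other sequence or a rescue with resistant Tex10 may tell these apart.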
